A study of Mus musculus with 26 samples.

How the data were processed

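Gene expression was measured in cultures of mouse embryonic stem cells with 26 microarrays of 2 colours, in which total RNA of a culture was labelled with Cy3 and a common reference RNA with Cy5, per the labels. The reference was a pool of RNA from cultured cell lines (Universal Mouse Reference) mixed with RNA of embryonic stem cells, per the labels' protocols, and every array had the same dye orientation. The arrays fell into 19 groups by cell line, doxycycline, day, sorted fraction and RNA extraction kit, and all groupings were taken from the sample titles. The labels call the arrays of one group biological replicates, but nothing states that they came from separate cultures, so p-values measure the spread between these arrays, which may be partly technical.

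The deposited scanner output gives the mean spot intensity and the local background intensity of each channel, read with Agilent Feature Extraction 9.5.1.1 and not yet normalized, per the file headers. The same output holds the log10 ratio of Cy5 over Cy3 that Feature Extraction computed from background-subtracted and dye-normalized signals, per the file headers. The authors also deposited a table of processed values whose scale and centring are not given in the sources used here. Set against the scanner values, it matched the Cy3 over Cy5 ratio in log10 with a constant added per probe. Over 16787 bright probes, the median SD across arrays of the table's value minus the log2 ratio, on the log2 scale, was 0.05, against 0.56 for the log2 ratio itself. The columns of that table had medians from 2.12 to 2.21 in log10. How its constant was set stays unknown, and it served as an alternative.

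From the raw intensities, background was corrected with normexp at an offset of 50, and each array was normalized by loess of the log2 ratio on mean intensity, with the 1417 control spots at weight 0, in limma 3.58.1 under R 4.3.3. Control spots and outlier spots were then left out, the latter numbering from 0 to 1795 per array, and no spot was saturated. Spots of one probe were averaged, which concerned 7 probes spotted 5 times each. Values are log2 of Cy3 over Cy5, so that a higher value means more RNA in the culture relative to the reference. A probe entered a fit where its Cy3 signal was well above background on at least 2 of the arrays of that fit. Cy3 was well above background for 62.9% to 79.9% of the probes of an array and Cy5 for 63.8% to 77.5%. The number of arrays limits the precision.

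The 42006 probes, each 60 bases long, are listed under probe identifiers only. The files do not pair these with genes, and none of the identifiers appears in the given table of RefSeq genes. The unit of every test was therefore the probe, where 1 probe per gene had been planned, several probes can belong to one gene, and no gene list could be tested. The rule for named genes asked for the largest increases and decreases among calls whose arms did not overlap. Without gene names it was applied to probes, for the comparison of the sorted fractions only, and limited to 2 probes that rose and 2 that fell, among 11044 called probes without overlap that were well above background on every array of both arms.

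Comparisons were fitted with limma (lmFit and eBayes, Benjamini-Hochberg adjusted p below 0.05 within each comparison). The 10 unsorted arrays of the Ascl1 line were fitted with day as a factor for induction and its change with day, and with Dox and day as a number for the trend. The 15 sorted arrays of day 14 shared one fit with a mean per line, Dox and fraction and an additive term for the kit. Residual degrees of freedom were 4 for induction and 9 for the sorted arrays. These designs, the threshold and the alternatives not marked as added were fixed before the data were examined. Groups without a second array are given as values with no test.

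Probe groups were then formed from the calls of one set of arrays, at 2-fold or more for the sorted comparisons, and followed in arrays that had no part in forming them. Their shifts were tested with limma's camera, which asks whether a group moved relative to all other probes, at a preset inter-probe correlation of 0.01 and again with the correlation estimated, and adjusted over 48 tests. These groups were chosen after the calls were seen. For single days, the median of a group was placed among the medians of 10000 random lists of the same size matched on mean Cy3 signal, as a description of those arrays.

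Alternatives covered Feature Extraction's own ratios, median centring in place of loess, the Cy3 channel alone with quantile normalization, the authors' table, the filter on dim probes, a 2-fold threshold, the scale of time, mirVana arrays only, slide and replicate number as blocks, single slides, one fit over all arrays and leaving out each array or day. Scale normalization between arrays, scan day as a block, slide as a block for the trend and the averaging of replicates on one slide were added after seeing the data. The scripts were tested on simulated arrays in which 100 probes were changed by known amounts. At a log2 change of 1, limma called 93% of them for induction, 80% for the fractions, 63% for Dox in the negative fraction, 93% for Ascl1 minus Smad7, 77% for Nr2f1 minus Ascl1 and 92% for the kit. At 0.1 log2 per day it called 48% for the trend. The simulated change was equal on all days, or linear with day for the trend, and the noise was independent between arrays. These shares may not hold for effects absent on some days or for replicates that share a slide.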

Results

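Mouse embryonic stem cells were driven towards neurons by switching on 1 of 3 transgenes, and their RNA was measured against a common reference. Ascl1 is a proneural transcription factor, Nr2f1 (COUP-TFI) is an orphan nuclear receptor, and Smad7 inhibits signalling by TGF-beta and BMP. Doxycycline (Dox) kept the transgene off, so cultures without it (Dox-) expressed the factor and cultures with it (Dox+) were the controls. After 3 days in alpha-MEM the cells were moved to a neural differentiation medium. On day 6, part of the cultures was sorted with magnetic beads against PSA-NCAM, the polysialylated cell adhesion molecule of neural precursors and immature neurons. Retained (PSANCAM-positive) and remaining (PSANCAM-negative) cells were then grown for 8 more days. The series title names markers of GABAergic neurons as the subject.

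The unsorted Ascl1 line was measured on days 3, 5, 7, 10 and 14, with 1 array per day for Dox- and 1 for Dox+. Sorted day 14 cells comprised positive fractions of the Ascl1 line (n = 5), the Smad7 line (n = 4) and the Nr2f1 line (n = 2), all Dox-, and negative fractions of the Ascl1 line with and without Dox (n = 2 each). One more array held MC1 cells on day 3 with Dox. RNA was extracted with Trizol or with the mirVana kit. Cy3 was well above background for 62.9% to 79.9% of the probes. The files give probes no gene names, so the expression of the transgenes themselves and of neuronal markers could not be read, and the results below are on probes and groups of probes.

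How far replicates differed depended on the slide. Over 19472 bright probes, the SD of Cy3 between replicates on one slide was 0.09 to 0.14 on the log2 scale in 5 pairs, against 0.06 to 0.11 for the reference RNA on the same arrays. Replicates on different slides differed by 0.37 to 0.42. In the Ascl1 positive fraction prepared with mirVana, replicates 1 and 2, both on slide 2, differed by 0.10 in Cy3 and 0.09 in Cy5, close to the noise of the reference, while replicate 3 lay on slide 7. The labels count them as separate biological replicates and they were kept so. Each sorted count is also given with arrays of one group on one slide averaged and counted once, an alternative chosen after seeing the data.

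The comparison of fractions asked how cells retained by the beads differed from cells not retained, both from induced Ascl1 cultures, which the labels do not pair. The fractions had different transcriptomes 8 days after sorting, with 19252 of 34712 probes called (limma), 10894 higher and 8358 lower in the positive fraction. Of these, 4510 were at least 2-fold higher and 3561 at least 2-fold lower. In terms of detection, 1343 probes were well above background on all 5 positive arrays and on neither negative array, 723 of them called higher. Another 332 were well above background on both negative arrays and on no positive array, 308 of them called lower. The positive arrays had more probes well above background in all, 69.2% to 74.5% against 65.4% and 68.0%, so these counts cannot be compared directly. With slide as a block 22159 probes were called, and 22192 within slide 2, the slide that held both fractions. Averaging the arrays of a group on one slide left 9197, all among the 19252 and in the same direction. The balance of higher against lower calls depended on the scaling, with 9775 higher and 10418 lower in the Cy3 channel alone and 9892 and 9717 in the authors' deposited values.

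The probe that rose most in this comparison, Z00025646-1 (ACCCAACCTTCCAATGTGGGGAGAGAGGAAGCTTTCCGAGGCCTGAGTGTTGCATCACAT), had a mean log2 ratio of 7.30 ± 0.67 (SD, n = 5) in the positive and 0.56 ± 0.36 (SD, n = 2) in the negative fraction. The fitted difference was 6.73 ± 0.38 (SE, adjusted p = 3.26e-08), about 106-fold. The next, Z00044277-1 (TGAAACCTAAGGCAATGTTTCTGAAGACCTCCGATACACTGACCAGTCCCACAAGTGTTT), differed by 6.56 ± 0.48 (SE, adjusted p = 2.69e-07). Among probes that fell, Z00045240-1 (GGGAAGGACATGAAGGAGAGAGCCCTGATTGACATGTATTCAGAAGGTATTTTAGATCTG) had -2.41 ± 0.30 (SD, n = 5) in the positive and 3.36 ± 0.10 (SD, n = 2) in the negative fraction, a difference of -5.78 ± 0.24 (SE, adjusted p = 2.87e-09). Z00031231-1 (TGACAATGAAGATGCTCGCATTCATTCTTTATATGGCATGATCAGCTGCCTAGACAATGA) differed by -5.36 ± 0.37 (SE, adjusted p = 1.74e-07). All 4 kept their direction and their call in each of the 22 alternatives run. Their choice as the largest differences without overlap on the same arrays made this outcome nearly certain, so it is no separate support.

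**Figure D1:**
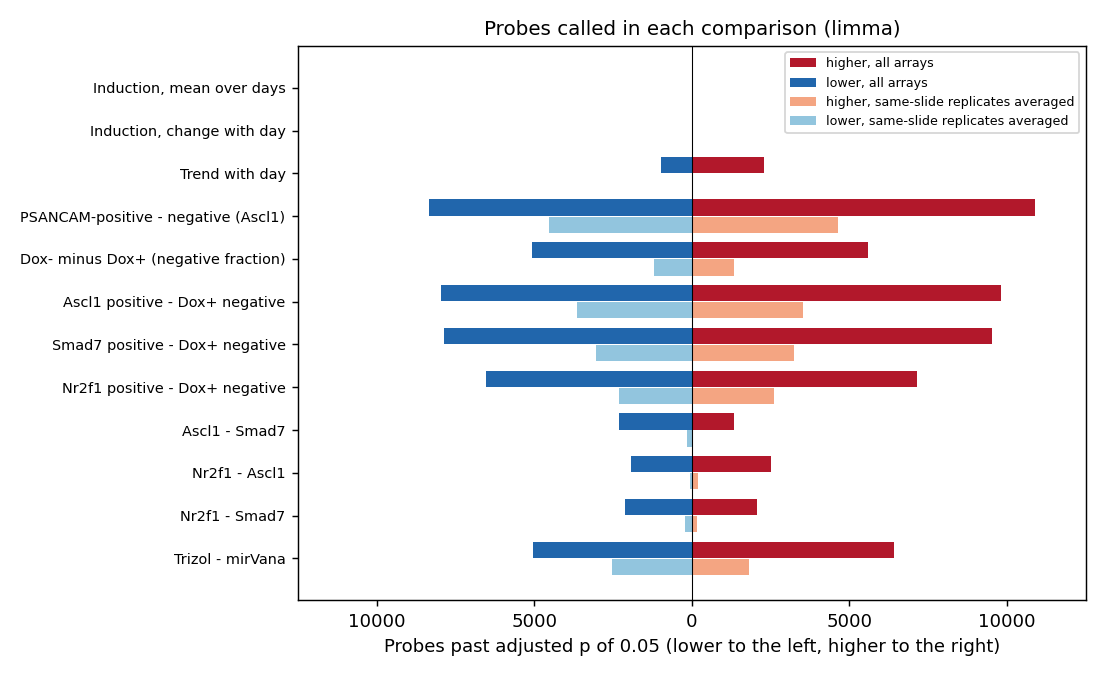
Number of probes called by limma in each of the 12 comparisons, lower to the left and higher to the right, for all arrays (dark bars) and, for the sorted comparisons, with replicates of a group on one slide averaged (pale bars). The fraction comparison had 19252 calls, the comparisons between transgenes 3638 to 4421, and induction over the unsorted days 0.

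The time course asked what Ascl1 induction did to unsorted cultures, with day as a block and so within slides. No probe passed the adjusted threshold over the 5 days (limma, 30779 tested, lowest adjusted p 0.0965), while 8385 (27.2%) had an unadjusted p below 0.05. Without day 3 the same test called 3771 probes, 2142 higher and 1629 lower in Dox-. On day 3 the cultures hardly differed. The SD over probes of Dox- minus Dox+ was 0.14 on day 3, and 0.46, 0.60, 0.61 and 0.52 on days 5, 7, 10 and 14. Only 2 probes were at least 2-fold higher and 0 lower on day 3. From day 5 on these numbers were 575 and 367, then 1346 and 399 on day 7, 1417 and 953 on day 10, and 1218 and 618 on day 14, from single arrays. In one fit over all 26 arrays, which takes the spread from the sorted replicates alone, 5226 probes were called for induction. This count holds no estimate of the variation between unsorted cultures.

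The probes that set the sorted positive fraction apart were followed in the unsorted cultures, where their shift passed the group test only at the preset correlation. Of the 4482 positive-fraction probes (at least 2-fold higher in that fraction) tested here, 86.8% were higher in Dox- over the days, with a median of 0.30 (camera, adjusted p = 8.74e-29 with the preset correlation, adjusted p = 0.192 with an estimated correlation). Their median Dox- minus Dox+ difference was -0.01 on day 3, 0.23 on day 5, 0.36 on day 7, 0.49 on day 10 and 0.50 on day 14. Among 10000 random lists, which spanned only -0.03 to -0.0099 on day 3, it lay at percentile 99.99 on that day and above all of them from day 5 on. Lists chosen for the extraction kit shifted too. The 587 Trizol-high and 1224 mirVana-high probes had medians of 0.10 and 0.07 for induction (camera, adjusted p = 0.000111 and 0.000317 preset, adjusted p = 0.596 and 0.838 with an estimated correlation). Both lay above all random lists on some days, the mirVana-high probes at 0.33 on day 5 and the Trizol-high probes at 0.26 on day 10. On day 10 the mirVana-high probes lay below all of them, at -0.13. In the Dox- cultures the median log2 ratio of the positive-fraction probes went from 0.10 on day 3 to 0.85 on day 14, and in Dox+ from 0.10 to 0.34. The 3496 negative-fraction probes (at least 2-fold lower in the positive fraction) had a median of -0.19 over the days, with 25.97% higher in Dox- (adjusted p = 2.70e-14 preset, adjusted p = 0.221 with an estimated correlation). Probe Z00025646-1 differed by 0.06 on day 3, 1.72 on day 5, 4.74 on day 7, 3.83 on day 10 and 3.62 on day 14. Z00044277-1 came later, with 0.44, 0.44, 0.82, 1.42 and 3.35 on the same days. Neither was called over the days (limma, adjusted p = 0.0965 and 0.123). Of the 2 negative-fraction probes, Z00031231-1 went against its group and was higher in Dox- by 1.95, 2.18 and 1.86 on days 7, 10 and 14, without a call over the days (adjusted p = 0.0965), and Z00045240-1 differed by -0.30, -0.45 and -0.76 (adjusted p = 0.276). Before day 7 Z00031231-1 was not well above background in Dox+.

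**Figure D2:**
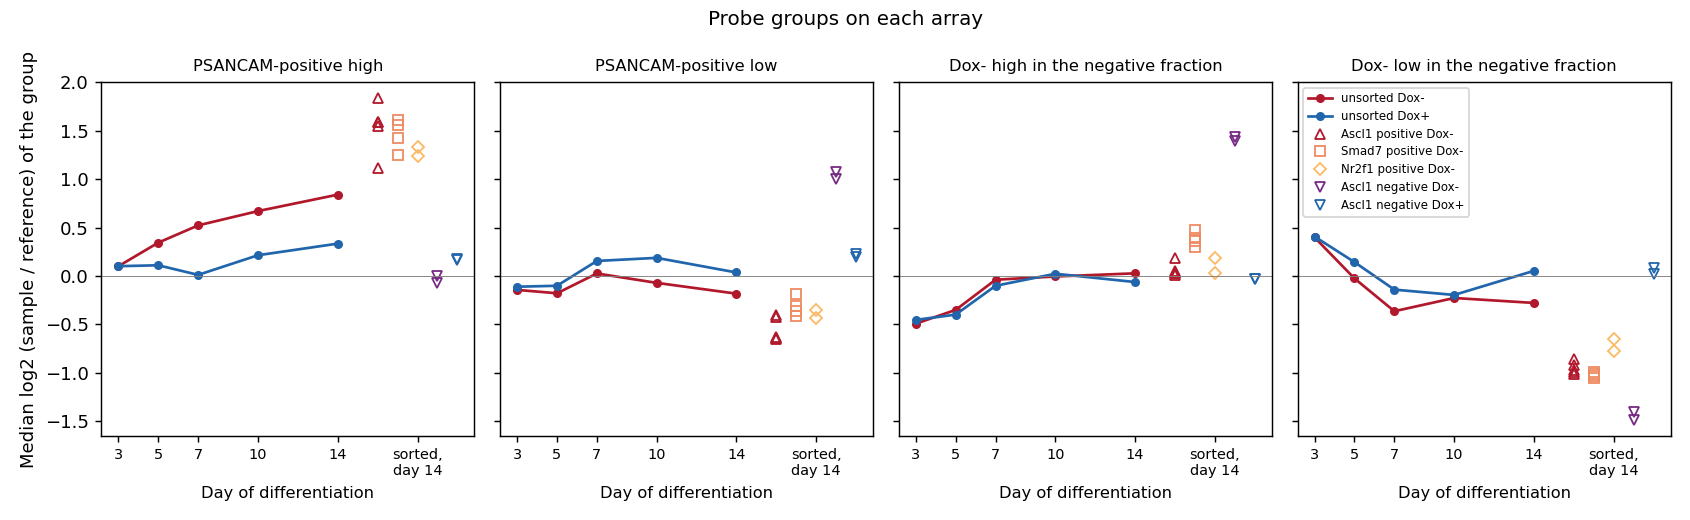
Median log2 ratio of sample over reference of 4 probe groups on each array, for unsorted Ascl1 cultures by day (lines, 1 array per point) and for the sorted day 14 arrays (open symbols, 1 per array). The groups were formed on sorted arrays of the Ascl1 line, so its symbols there are not independent of that choice. The positive-fraction probes had the same median in Dox- and Dox+ on day 3, 0.10, and 0.85 against 0.34 on day 14.

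Whether the induction effect changed with day was tested as a slope. No probe was called (limma, lowest adjusted p 0.331, 2959 with an unadjusted p below 0.05). As a group, the positive-fraction probes had a median slope of 0.04 log2 per day, 79.3% of them above 0 (camera, adjusted p = 4.84e-21 preset, adjusted p = 0.182 with an estimated correlation). The negative-fraction probes had a median slope of -0.02 per day (adjusted p = 1.57e-11 preset, adjusted p = 0.221 with an estimated correlation). One fit over all 26 arrays, with the spread again taken from the sorted replicates alone, called 361 probes.

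With Dox- and Dox+ in one fit, 3284 probes were called for a trend with day (limma), 2290 rising and 994 falling. No called slope reached 2-fold per day. Probe Z00031231-1 was called as rising (adjusted p = 0.00216), but was not well above background in either culture on day 3 or in Dox+ on day 5, so no slope is given. It reached 1.44 in Dox- and -0.43 in Dox+ on day 14. Z00025646-1 rose by 0.39 ± 0.09 per day (SE, adjusted p = 0.0266) and Z00044277-1 by 0.38 ± 0.07 (SE, adjusted p = 0.0161). Day went with slide, since day 3 had a slide of its own and days 5 and 7 shared one, as did days 10 and 14. With slide as a block, added after seeing the data, no probe was called (limma, 977 with an unadjusted p below 0.05). The slopes, then taken from pairs of days on one slide, kept their sign in 2245 of the 2290 rising and 927 of the 994 falling probes. Their medians went from 0.13 to 0.10 and from -0.08 to -0.05 log2 per day, while the median SE grew from 0.03 to 0.07 and from 0.02 to 0.04. The same arrays had a part in choosing these probes. Without day 3, 5 or 10 there were 1476, 1324 and 597 calls. With median centring the split was 2823 rising and 397 falling, in the Cy3 channel alone 1859 and 1772, and in the authors' deposited values 1726 and 1220.

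The negative fractions asked what induction did to the cells the beads had not retained. Ascl1 Dox- and Dox+ negative cells differed in 10682 of 34712 probes (limma), 5601 higher and 5081 lower in Dox-, with 2170 and 2041 at 2-fold or more. The 2 probes that fell most in the positive fraction were, among the sorted cells, high in this Dox- negative fraction alone. Z00045240-1 was higher than in Dox+ by 4.18 ± 0.27 (SE, adjusted p = 5.49e-07) and Z00031231-1 by 4.89 ± 0.42 (SE, adjusted p = 4.09e-06). The same 2 Dox- negative arrays had a part in choosing these probes, so these values are not independent of that choice. Each arm had 2 arrays on a slide of its own, and no slide held both. With slide as a block, estimated through the positive arrays, 13635 probes were called, 6610 higher and 7025 lower, 7568 of them shared with the 10682. Averaging replicates on one slide left 2520, and leaving out Dox- negative replicate 1 left 7042.

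Probes at least 2-fold higher (raised) or lower (lowered) in Dox- than in Dox+ negative cells were distributed differently over the other sorted cells. They were chosen on the negative arrays for that difference, and Dox and slide went together there. The 2170 raised probes had a mean of array medians of 1.42 ± 0.03 (SD, n = 2) in the Dox- negative fraction and -0.03 in Dox+ (n = 2). In the positive fractions they had 0.06 ± 0.07 for Ascl1 (SD, n = 5), 0.38 ± 0.07 for Smad7 (SD, n = 4) and 0.10 ± 0.11 for Nr2f1 (SD, n = 2). The 2041 lowered probes had -1.44 ± 0.06 (SD, n = 2) and 0.05 ± 0.04 (SD, n = 2) in the negative fractions, and were low in all 3 positive fractions, at -0.95 ± 0.06 for Ascl1, -1.02 ± 0.03 for Smad7 and -0.71 ± 0.08 for Nr2f1 (SD). In the unsorted cultures the raised probes tested there had a median of 0.02 for induction (camera, adjusted p = 0.599) and a median slope of 0.05 log2 per day for the trend, which had no calls with slide as a block (adjusted p = 3.92e-16 preset, adjusted p = 0.181 with an estimated correlation). The lowered probes had a median of -0.13 for induction (adjusted p = 1.35e-05 preset, adjusted p = 0.417 with an estimated correlation) and -0.04 per day for the trend (adjusted p = 1.68e-09 preset, adjusted p = 0.366 with an estimated correlation).

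Positive cells of each transgene were next set against the Dox+ negative fraction of the Ascl1 line, the only replicated day 14 cells with a repressed transgene. This joins induction, sorting and, for Smad7 and Nr2f1, the cell line. The 3 fractions moved far from the control and in similar directions. Ascl1 cells differed in 17782 probes (9831 higher, 7951 lower), Smad7 cells in 17403 (9520 and 7883) and Nr2f1 cells in 13666 (7136 and 6530). The positive-fraction probes had a mean of array medians of 1.46 ± 0.16 in Smad7 (SD, n = 4) and 1.29 ± 0.07 in Nr2f1 (SD, n = 2), near the 1.54 ± 0.26 of Ascl1 (SD, n = 5) on which they were chosen, and 0.17 in the control (n = 2). Probe Z00025646-1 was higher by 7.91 ± 0.38 in Ascl1, 7.69 ± 0.40 in Smad7 and 6.51 ± 0.45 in Nr2f1 cells (SE, limma adjusted p = 1.38e-08, 3.11e-08 and 7.19e-07). Probes rising with day in the time course had medians of 0.92, 0.92 and 0.86 in these comparisons, and those falling with day -0.66, -0.78 and -0.74 (camera, highest adjusted p = 8.44e-15 preset, 0.113 with an estimated correlation).

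Ascl1 and Smad7 cells shared 8030 probes called higher and 6655 called lower, where independent lists would share 2696 and 1806, and 12 and 59 were called in opposite directions. Across probes, the 2 differences correlated at 0.933, against 0.712 in simulated arms with no effect that share the control arrays, with a covariance of 0.899 against 0.025. The correlation was 0.914 for Ascl1 and Nr2f1 (simulated 0.623) and 0.886 for Smad7 and Nr2f1 (simulated 0.610), and probes are not independent replicates. With the 2 control arrays split, 1 for each comparison, the correlations were 0.922 and 0.924 for Ascl1 and Smad7 (simulated 0.048 and 0.052), 0.897 and 0.908 for Ascl1 and Nr2f1, and 0.870 and 0.880 for Smad7 and Nr2f1. Both controls lay on slide 3, so part of the excess may come from what they share there. The Dox effect in the negative fraction and the Ascl1 positive difference, which also share them, correlated at 0.215 (simulated 0.567), with a covariance of 0.148 against 0.022, and at 0.218 and 0.194 with the controls split. They shared 2935 probes called lower (1164 for independent lists) and 1916 called higher (1586), while 1483 were higher in the first and lower in the second (1283) and 855 the reverse (1439). With slide as a block, 16257, 14508 and 12756 probes were called for Ascl1, Smad7 and Nr2f1. Slide 3 alone called 19372 for Ascl1, but set 1 Trizol positive array against 2 mirVana control arrays and so cannot be told apart from the kit. Of the 13385 it shared with all arrays, 11972 had the same direction. With replicates on one slide averaged, the counts were 7182, 6284 and 4949. The balance of higher against lower calls turned with several scalings. For Ascl1 it was 8513 higher and 10338 lower in the Cy3 channel alone, 9303 and 9500 with Feature Extraction ratios, 7410 and 7874 with median centring and 8705 and 9164 in the authors' deposited values. For Smad7 it was 7640 and 9585 in Cy3 alone, 8385 and 8893 with Feature Extraction ratios and 7929 and 8460 in the authors' values, and for Nr2f1 6050 and 7852 in Cy3 alone and 6084 and 6672 with slide as a block.

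Within the positive fraction, transgenes were compared with each other. These differences were smaller than those between fractions, with medians of the absolute log2 difference of 0.13 for Ascl1 minus Smad7, 0.18 for Nr2f1 minus Ascl1 and 0.16 for Nr2f1 minus Smad7, against 0.43 between fractions. Ascl1 and Smad7 differed in 3638 probes (limma), 1327 higher and 2311 lower in Ascl1, with 196 and 559 at 2-fold or more. Nr2f1 and Ascl1 differed in 4421 (2500 higher and 1921 lower in Nr2f1), and Nr2f1 and Smad7 in 4187 (2073 and 2114). The 2 probes that rose most in the Ascl1 positive fraction were lower in Nr2f1 than in Ascl1, Z00025646-1 by -1.40 ± 0.36 (SE, adjusted p = 0.0271) and Z00044277-1 by -1.86 ± 0.46 (SE, adjusted p = 0.0202). Between Ascl1 and Smad7 they differed by 0.22 ± 0.29 and -0.12 ± 0.37 (SE, adjusted p = 0.711 and 0.889). Z00045240-1 was lower in Ascl1 than in Smad7 by -1.21 ± 0.18 (SE, adjusted p = 0.00129). The Ascl1 arrays had a part in choosing these named probes. The 194 probes at least 2-fold higher in Ascl1 than in Smad7 and tested in the time course rose there with day, by a median of 0.10 log2 per day (camera, adjusted p = 3.77e-16 preset, adjusted p = 0.0302 with an estimated correlation). The opposite list, 540 probes higher in Smad7, also had a positive median of 0.05 (adjusted p = 1.03e-09 preset, adjusted p = 0.0797 with an estimated correlation), as had the probes higher in Nr2f1 than in Ascl1 (0.04) and in Ascl1 than in Nr2f1 (0.07), so a positive median was not limited to the Ascl1 list. With slide as a block the trend itself had no calls (limma, 977 with an unadjusted p below 0.05).

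The number of calls between transgenes depended strongly on how slides and replicates were treated. For Ascl1 minus Smad7 it was 5384 with slide as a block (2774 higher, 2610 lower), 9092 with scan day as a block (5180 and 3912) and 174 with replicates on one slide averaged. Within slide 7 it was 12736 (8041 and 4695), where the kit term leaves 1 Ascl1 array against 2 of Smad7. It was 7000 without Ascl1 Trizol replicate 2, 2263 without Smad7 Trizol replicate 1, and 2130 and 2128 without Smad7 mirVana replicates 1 and 2. Nr2f1 minus Ascl1 had 4932 calls with slide as a block, 14167 with scan day as a block and 247 after averaging, and no slide allowed it to be tested alone. Its balance turned to 2111 higher and 2821 lower with slide as a block, 5735 and 8432 with scan day and 2161 and 2365 with mirVana arrays only. It had 6990 (3272 and 3718) without Ascl1 Trizol replicate 1, and 2752 and 978 without the Trizol and the mirVana array of Nr2f1. Nr2f1 minus Smad7 had 7841 with slide as a block, 9599 within slide 8, again 1 array against 2 once the kit term is fitted, 11126 with scan day as a block, 375 after averaging, and 2575 and 1758 without those Nr2f1 arrays. Scale normalization left 1803, 2189 and 2118. Median centring moved the balance to 505 higher and 2093 lower, 4231 and 617, and 2169 and 1307.

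The extraction kit was compared within the positive fractions, which held 5 Trizol and 6 mirVana arrays. The labels do not say whether both kits were used on the same cultures or sorts, so kit and culture cannot be told apart. Between kits 11485 probes differed (limma), 6431 higher and 5054 lower with Trizol, of which 615 and 1226 by 2-fold or more, against 4510 and 3561 between fractions. The kit difference went with the same probes in each transgene. Here it was taken from 1 Trizol and 1 mirVana array on slide 7 for Ascl1 and on slide 8 for Nr2f1. For Smad7, Trizol arrays lay on slide 8 and mirVana arrays on slide 7, so kit went with slide. Across probes the kit difference correlated at 0.898 between Ascl1 and Smad7, 0.771 between Ascl1 and Nr2f1 and 0.796 between Smad7 and Nr2f1. Of 1340 probes with a 2-fold difference in both Ascl1 and Nr2f1, 99.9% had the same sign. These values have no replicate check for Ascl1 and Nr2f1. No probe was called for a kit difference that itself differed between Ascl1 and Smad7 (limma, 0 of 34708, 1593 with an unadjusted p below 0.05). None of the 4 named probes was called for the kit, with differences from -0.26 to 0.30 and a lowest adjusted p of 0.404. The count was 13006 with slide as a block and 4351 (1813 higher and 2538 lower) with replicates on one slide averaged. Within slide 7 the kit difference rests on 1 Trizol and 1 mirVana array of Ascl1. Within slide 8 it rests on 1 Trizol and 1 mirVana array of Nr2f1, so no counts are given for single slides. Median centring gave 20071 calls, split 15620 to 4451.

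**Figure D3:**
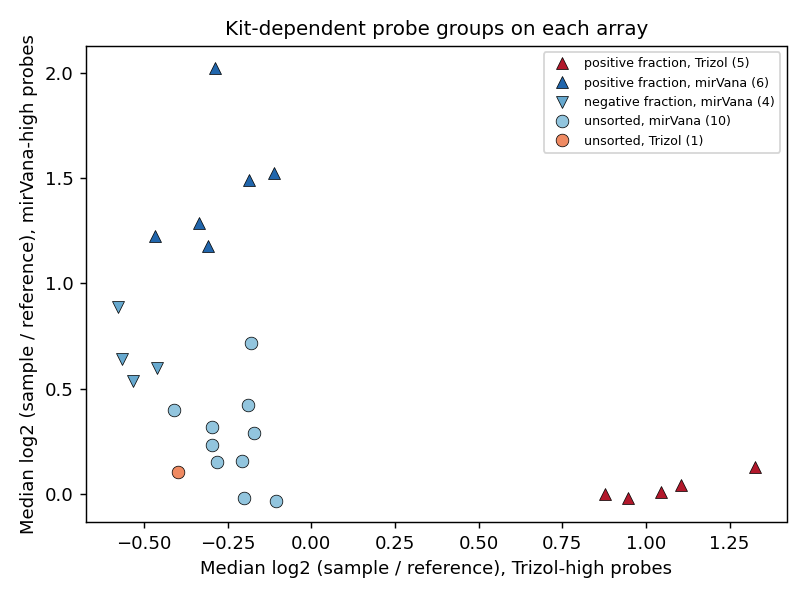
Median log2 ratio of the 615 probes at least 2-fold higher with Trizol (horizontal axis) and of the 1226 at least 2-fold higher with mirVana (vertical axis), 1 symbol per array. The positive-fraction arrays, on which the probes were chosen, split by kit, while the unsorted MC1 array prepared with Trizol, at -0.40 and 0.11, lay among the unsorted mirVana arrays.

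MC1 cells on day 3 with Dox were measured on 1 array, and differed from the Ascl1 line on day 3 with Dox in line, kit and slide at once. The SD over probes of the difference was 0.52, with 608 probes at least 2-fold higher and 1099 at least 2-fold lower in MC1, and has no replicate check. The positive-fraction probes were lower in MC1 by a median of -0.16, below all 10000 random lists, and the negative-fraction probes had a median of -0.06, at percentile 52.8. A low median was not limited to the positive-fraction probes. The Trizol-high probes had -0.13, also below all lists, and the mirVana-high probes -0.06, at percentile 9.66. The probes raised and lowered in Dox- of the negative fraction had -0.09 and -0.05, at percentiles 0.02 and 99.93.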

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

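The tests on the share of calls and on the Cy5 channel within slide 2 were chosen only after the result was seen. The Cy5 channel held the same reference RNA on every array and is the denominator of every log ratio. Fitted alone in the same designs, it still separated groups of arrays. For the PSANCAM-positive against the negative fraction it gave 1989 called probes (limma), 905 higher and 1084 lower, 1734 of which were also called in the log ratio. For Trizol minus mirVana it gave 1836, of which 594 were higher and 1242 lower, with 1325 shared. Of all probes tested, the log ratio called 55.5% for the fractions and 33.1% for the kit. The Cy5 differences were small, with a median absolute log2 difference of 0.06 for the fractions and 0.04 for the kit, against 0.43 and 0.18 in the log ratio.

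If differences between slides or scans made most of the calls, the reference should give at least 50 percent as many, and under 10 percent if they did not. It gave 4.87% for Ascl1 minus Smad7 and 5.03% for Dox- minus Dox+ in the negative fraction, below the lower bound. This speaks only to effects of slides and scans that reach both channels, which the ratio largely removes in any case. Cultures, RNA, Cy3 labelling or Cy3 scanning that went with the slides leave no trace in the reference. Replicates on different slides differed by 0.37 to 0.42 in Cy3 and by 0.09 to 0.11 in Cy5, so slides stay open as a source of those calls. For the fractions the reference gave 10.3%, just above the lower bound. Slide 2, scanned on 1 day, held 2 arrays of each fraction, and within it 95.2% of the 19252 calls were made again in the same direction, while Cy5 gave 1137 calls there against 22192 in the log ratio. This argues against differences between slides or scan days as the source of most calls between the fractions. What else went with the fractions, a biological difference between the sorted cells included, stays open.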

How the results depend on the processing

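The tests added after seeing the data were scale normalization, scan day as a block, slide as a block for the trend and averaging of replicates on one slide. Of the counts under alternatives to comparisons with calls, 172 stayed within 1.5 times the value reported, 34 fell below and 12 rose above. The 2 comparisons without calls, induction and its change with day, had 0 calls in 13 and 14 of 15 alternatives each. The cause of a change was not tested unless its construction shows it. Cy3 was well above background for at least 62.9% of the probes on every array, and below that level differences are only bounds. The 4 named probes kept their direction and their call in every alternative run for them, which their choice on the same arrays made nearly certain. Of the group medians, 7 were run again in 5 other scalings. For induction and its change with day they were those of the positive-fraction and negative-fraction probes. For the trend they were those of the probes raised and lowered in Dox- of the negative fraction and of the probes higher in Ascl1 than in Smad7. These 7 medians kept their direction and, at the preset correlation, their call. With an estimated correlation only the last was called (adjusted p = 0.0302), and the other 6 were not (adjusted p = 0.181 to 0.366).

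Requiring 2-fold left 0 calls for the trend, where it asked for 2-fold per day and so says nothing on the change over all days. It left 8071 for the fractions and 4211 for Dox in the negative fraction. For Ascl1, Smad7 and Nr2f1 positive cells against the Dox+ negative fraction it left 6825, 6927 and 5708. It left 755 for Ascl1 minus Smad7, 752 for Nr2f1 minus Ascl1, 1236 for Nr2f1 minus Smad7 and 1841 for the kit. This is a stricter threshold by construction. Averaging replicates on one slide, which leaves fewer arrays and 4 residual degrees of freedom, gave 9197, 2520, 7182, 6284, 4949, 174, 247, 375 and 4351 for the same comparisons after the trend, in that order. One fit over all 26 arrays called 5226 for induction, 361 for its change with day and 10886 for the trend. Rank of time gave 5804 for the trend, and slide as a block 0 (limma, 977 with an unadjusted p below 0.05).

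Scale normalization gave 1803, 2189 and 2118 for Ascl1 minus Smad7, Nr2f1 minus Ascl1 and Nr2f1 minus Smad7, and scan day as a block 9092, 14167 and 11126. Slide 7 alone called 12736 for Ascl1 minus Smad7. Nr2f1 minus Smad7 had 7841 with slide as a fixed block, 6870 as a random block and 9599 on slide 8 alone. Median centring gave 20071 for the kit. Leaving out each day in turn gave 0 to 3771 calls for induction, 0 for its change with day, and 597 to 3395 for the trend. Leaving out each array in turn gave 13576 to 21221 for the fractions, 7042 to 8404 for Dox in the negative fraction, 2128 to 7000 for Ascl1 minus Smad7, 978 to 6990 for Nr2f1 minus Ascl1, 1758 to 3067 for Nr2f1 minus Smad7 and 9637 to 12740 for the kit. Where this left an arm with 1 array, that array was assumed to vary like the others.

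Replicate numbers showed no clear pairing of the samples. The difference between replicates 1 and 2 correlated across probes at -0.22 to 0.15 over 15 pairs of groups, above 0.1 in 5. In most of these groups both replicates lay on one slide and differed little more than the reference, so this cannot exclude a pairing. With replicate number as a replicate block the counts were 18434 for the fractions, 11363 for Dox in the negative fraction, 16855, 17958 and 14617 for the positive cells against the Dox+ negative fraction, 3964, 3518 and 3816 between the transgenes and 11127 for the kit, or 8153 for the kit with transgene by replicate number. No count moved by more than 1.5 times. Quantile normalization of the average intensities leaves log ratios as they are, and the mean over probes of a gene and the gene list shifts were not run, since the files do not pair probes with genes.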

Other observations

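The tests below on the number of probes at an unadjusted p, on arms swapped within days, on averages of arrays on one slide and on the C content of probes were chosen only after the result was seen, and the correlations and values of the other paragraphs are descriptions. The daily effect of Ascl1 in unsorted cultures came to resemble the difference between sorted positive cells and the Dox+ negative fraction. Across probes, Dox- minus Dox+ correlated with that difference at 0.05 on day 3, 0.40 on day 5, 0.63 on day 7, 0.59 on day 10 and 0.77 on day 14. With the difference between the fractions the values were 0.04, 0.31, 0.49, 0.53 and 0.56. With the Dox effect in the negative fraction they stayed low, at 0.01, 0.08, 0.11, -0.0039 and 0.21. The unsorted arrays share no array with the sorted ones, probes are not independent replicates, and each day is 1 pair of arrays.

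The trend with day in the unsorted cultures had no calls with slide as a block. Without that block, its called probes also differed as groups between Dox- and Dox+ negative cells at the preset correlation. The 2007 rising probes tested there had a median of 0.36 and the 858 falling ones of -0.38 for Dox- minus Dox+ in the negative fraction (camera, adjusted p = 7.18e-09 and 7.07e-10 preset, adjusted p = 0.192 and 0.220 with an estimated correlation). For the positive against the negative fraction their medians were 0.55 and -0.22 (adjusted p = 0.00106 and 9.68e-06 preset, adjusted p = 0.462 and 0.402 with an estimated correlation). Between Ascl1 and Smad7 the rising probes had a median of 0.01 (adjusted p = 0.518) and the falling probes one of 0.12 (adjusted p = 0.00576 preset, adjusted p = 0.616 with an estimated correlation).

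The absence of calls for induction over the 5 days was set against other splits of the 10 unsorted arrays into 5 and 5, with 100 drawn. Since the real split had 0 calls, all 100 of 100 reach its count whatever the data, and the calls decide nothing about chance. For probes at an unadjusted p below 0.05, 2 of 100 gave as many as the real 8385, itself included, but these splits can put both arrays of a day in one arm. Swapping the arms within days keeps the pairs and allows 16 splits, too few for a share under 0.05, with 8385 such probes in the real one, 1 of 16, and 7073 in the highest other, which swapped day 3. The highest of the 100 drawn had 10239 such probes, and 5615 calls where the real one had 0, which points to a structure of the samples. It differed from the real one in taking the day 3 Dox+ culture in place of the day 5 Dox- culture. With day as a block it then rests on days 7, 10 and 14, and a candidate explanation is that an effect absent on day 3 inflates the spread of the average, as the 3771 calls without day 3 may also reflect.

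Other splits were also drawn for the larger comparisons. Of 100 splits of the 9 Ascl1 and Smad7 positive arrays into 5 and 4, only the real one, 1 of 100, gave as many as 3638 calls, and the highest other, which joined all 4 arrays of slide 7, had 2151. These splits take replicates on one slide as independent. With arrays of one group on one slide counted once, the 15 splits of 6 averages are too few for a share under 0.05. The real one then had 174 calls, reached by 2 of 15, and the highest other, which set slides 7 and 8 against slides 2 and 3, had 1164, several times the real count, which points to a structure that follows the slides. For the kit, 1 of 100 splits of the 11 arrays gave as many as 11485, the real one, and the highest other had 85. Counted once, 1 of the 34 splits that could be fitted gave as many as 4351, the real one, and the highest other had 510. Chance is thus an unlikely source of the kit calls, though these splits take averages that share a slide as independent. Cultures or sorts that went with the kit stay open.

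Probes that differed between the kits also differed in base composition. The 1226 probes higher with mirVana had on average 32.8% C and 19.3% G, the 615 higher with Trizol 19.01% C and 23.5% G, and all others 22.3% and 22.5%. The kit difference correlated with C content across probes at -0.347, and C content accounted for 15.9% of its variance. Removing a smooth trend on GC content left 12273 calls and on C content 11738, against 11485 before. At 2-fold or more the calls fell from 1841 to 1685 with GC removed and to 1374 with C removed. Neither trend can thus be the whole source, though C content may account for part of the larger differences. With C removed the mirVana-high probes still had a median of -1.11, from -1.36 before. What else may set these probes apart, including cultures or sorts that differed between the kits, was not tested, and no biological explanation was tested.

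The same probes did not split other arrays by kit. On the 5 Trizol positive arrays the mirVana-high probes had medians of -0.02 to 0.13 and on the 6 mirVana positive arrays 1.18 to 2.02, the arrays on which they were chosen. On the 4 negative arrays, all mirVana, they had 0.54 to 0.89, and on the 10 unsorted mirVana arrays -0.03 to 0.72. The Trizol-high probes were at 0.88 to 1.32 on the Trizol positive arrays and at -0.40 on the unsorted MC1 array, the only other array prepared with Trizol.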
